A study of Mus musculus with 3 samples.

How the data were processed

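RNA was measured in 3 splenic lymphomas of the pBIC mouse, a C57BL/6 model of the activated B cell (ABC) subtype of diffuse large B cell lymphoma. Its B cells carry floxed alleles of Trp53 and of Prdm1, which encodes BLIMP1, and a constitutively active IKK2 allele behind a floxed stop. Cre recombinase is expressed from the Ighg1 (C gamma 1) locus. Spleens of moribund mice were dissociated and red cells were lysed. Cells positive for B220 and the GFP reporter were sorted after exclusion of dead cells with 7AAD, per the labels' protocols. RNA was extracted with TRIzol, and polyadenylated mRNA was selected with oligo-dT and sequenced on a DNBseq instrument as single reads of 50 nt. The design text also names sorted germinal centre B cells of immunised mice as normal controls. These were not analysed here, so no lymphoma is compared with normal B cells.

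The deposited values are raw read counts per gene, 1 library per file, with no normalization. FastQC, STAR 2.5.2b, featureCounts 1.6.0 and the mouse genome build mm10 are named, per the submitters' processing notes. The role and settings of each tool, the use of strand, the annotation release and the rule that chose the listed genes are not given in the sources used here. Each file lists 37646 genes with an identifier, a biotype and a symbol, of which 12146 had no count in any tumour. Among the identifiers, 36825 were in GENCODE release M21 (GRCm38, the same assembly as mm10) with the same version, and 37536 were there when the version was ignored. The remaining 110 genes had no length. Coordinates are 1-based and come from release M21.

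The featureCounts default leaves out reads that map to several places, and whether that default was kept is not given. Counts on near-identical genes, such as immunoglobulin V genes, haemoglobin genes, histocompatibility genes and guanylate-binding proteins, are therefore uncertain. The same holds for genes that overlap on opposite strands. Reads of 50 nt that span a V to J junction, or that differ from the reference by somatic mutation, can be lost. Counts per gene cannot separate a deleted floxed exon or a transgene from the endogenous gene.

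Total counts per library were 15141009, 15022902 and 15074513 in tumours 1, 2 and 3, and 21549, 20504 and 21311 genes had at least 1 count. A gene with no count could still have been present at up to 3 counts, which is 0.194, 0.209 and 0.196 CPM (read counts scaled to a common library size). Mitochondrial genes took 5.59%, 5.06% and 4.86% of counts, and immunoglobulin genes took 1.22%, 1.31% and 1.55%. Of 13 mitochondrially encoded genes 6 stayed below 1 CPM in every tumour, so the mitochondrial shares may be too low. The libraries carry no molecular identifiers, so intervals and floors cover counting error only. The tumours form 1 group and are numbered in accession order, which pairs nothing. The labels give each library its own number without stating outright that the animals were separate or unrelated. The variability test described below thus measures the spread between these samples, against genes of similar abundance. The sign-flip test asks whether a difference between genes keeps its direction in them. Fisher's exact test runs over genes, so its p-value measures no spread between samples.

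Counts were scaled to CPM with TMM factors of 1.023, 0.9595 and 1.018 (R 4.3.3, edgeR 4.0.16). The plan, fixed before the data were examined, gave list levels in TPM from lengths in the files. The deposited counts come without lengths, so list levels and gene levels are given as CPM, which is not corrected for length. TPM from the union exon lengths of release M21 was used for the differences between genes within a tumour and for the choice of named genes.

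With 1 group there is no contrast to fit. An intercept-only edgeR model was fitted to the 11478 genes that passed filterByExpr, and the residual deviance on 2 degrees of freedom was divided by the robust prior variance at the abundance of the gene. The ratio was tested one-sided against an F distribution with 2 and 15.8 degrees of freedom, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The test asks whether a gene varied more between tumours than genes of similar abundance did. With 1 group, filterByExpr asks for the minimum count in every tumour, which removes genes near absent in 1 tumour. A filter on a mean count of at least 10 was therefore added after seeing the data. The common biological coefficient of variation was 0.345, and the trend ran from 0.261 to 0.480.

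On simulated counts for the same 11478 genes, with 200 genes of a mean count of at least 50 changed in 1 tumour in each of 5 runs, the variability test recovered 13.2% of genes changed 4-fold, 62.8% of those changed 8-fold, 96.8% of those changed 16-fold and 99.6% of those changed 32-fold. At most 6 calls in a run were false, and at most 1 gene was called in a run with no changed gene. The simulated genes were filtered on a mean count of at least 10, not with filterByExpr. In the tumours themselves that filter led to 0 calls. Dispersions were drawn from the fitted prior, and changes were upward only. These rates thus do not carry over to the calls made with filterByExpr. In a simulation of list deviations, 20 of 20 raised lists were found above the random lists and 1 of 20 unchanged lists fell outside their central 95%. These lists were random genes, and the raised ones were shifted uniformly. Few unchanged ones outside follow by construction, so neither figure tells how often a list of co-expressed genes falls outside.

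Before the data were examined, 38 gene lists with 377 distinct genes were fixed from general knowledge, of which 375 genes were in the files. The absent symbols were Ccl19 and Ccl21a. For each list, members with at least 1 CPM in all 3 tumours were counted. The median CPM of the list was ranked among 10000 random lists of the same size drawn from genes with a mean above 0.1 CPM. The deviation of a list in a tumour is the median over its tested members of log2 CPM (prior count 2) minus the mean of the 3 tumours. It was ranked among 10000 random lists matched on mean expression in 20 bins, for lists with at least 3 tested members. These percentiles describe the libraries and are not p-values. Overlap of lists with variable genes was tested with Fisher's exact test and adjusted over lists.

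Shares of immunoglobulin counts have exact Clopper-Pearson 95% intervals, and V gene shares were not computed below 100 counts. Differences between genes or lists within a tumour used log2(TPM + 1) and a two-sided exact sign-flip permutation test, whose smallest possible p with 3 tumours is 0.25. The named genes follow a fixed rule. It takes the engineered genes, the immunoglobulin constant genes with the leading V genes, and the 20 most abundant genes other than immunoglobulin, mitochondrial and ribosomal protein genes. It also takes the 24 genes with the smallest variability p that have a characterised symbol and are not immunoglobulin segments, and the highest, variable and undetected members of each list. Some genes that the rule takes are not reported here. Joining genes and genes with provisional symbols were named after their values were seen.

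Alternatives tried were DESeq2 1.42.0 size factors and dispersion trend, no filter or a filter at 5 CPM, a chi-square test, raw library sizes, omission of immunoglobulin genes, TPM without immunoglobulin and mitochondrial genes, random lists from genes above 1 CPM, other pseudocounts and prior counts, division by gene length and omission of each tumour in turn. Removal of a per-library trend on gene length and GC content, list levels in TPM over all genes and the filter on mean count were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.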

Results

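Messenger RNA was counted per gene in sorted B220+GFP+ lymphoma cells from the spleens of pBIC mice, 1 library for each of 3 tumours, with 15022902 to 15141009 counts per library. The labels describe the model as a counterpart of the ABC subtype of diffuse large B cell lymphoma, in which NF-κB signalling is high and plasma cell differentiation is blocked. All libraries belong to 1 group. The values below describe what the tumours had in common and where they differed from each other, as mean ± SD over n = 3 unless single tumours are named.

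The engineered genes were read first. Trp53, the tumour suppressor deleted in the model (ENSMUSG00000059552.13, chromosome 11, 69580359 to 69591873), had 35.4 ± 22.6 CPM, with 23.9, 20.9 and 61.5 CPM in tumours 1, 2 and 3. Prdm1, which encodes the plasma cell regulator BLIMP1 (ENSMUSG00000038151.13, chromosome 10, 44437177 to 44528501), had 11.9 ± 7.17 CPM, with 6.41, 20.0 and 9.35 CPM. Ikbkb, the gene of the kinase IKK2 (ENSMUSG00000031537.15, chromosome 8, 22659212 to 22706589), had 371 ± 79.5 CPM. Its partners in the IKK complex, Chuk and Ikbkg, had 134 ± 26.9 and 50.2 ± 7.24 CPM. None of the 6 genes of this set, Ighg1 included, passed the edgeR variability test, where the adjusted p was 0.636 for Trp53 and 0.966 for Prdm1. Counts over whole genes include any transcript of a recombined allele, so these values check neither the deletions nor the transgene.

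After division by union exon length, the difference Ikbkb minus Chuk was -0.23, -1.06 and -0.01 in log2(TPM + 1) in tumours 1, 2 and 3. Its mean was -0.43 ± 0.55 (SD, n = 3), with a two-sided exact sign-flip p of 0.25, the smallest that 3 tumours allow. The mean was -0.12 without tumour 2. Without division by length the difference was 1.46, in the opposite direction. The union exon length of Ikbkb in the annotation is 19078 nt and that of Chuk is 5087 nt. Such a length joins the exons of all annotated transcripts of a gene. The transcripts present here were not measured, so the sign of the difference is not settled.

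The immunoglobulin transcripts of all 3 tumours were dominated by the same genes. The constant gene Ighg3 (ENSMUSG00000076615.4, chromosome 12, 113356224 to 113361232, reverse strand) held 85.6% ± 4.02 (SD, n = 3) of heavy-chain constant counts. Its share was 85.7% in tumour 1 (95% Clopper-Pearson interval 85.5 to 86.0%), 81.5% in tumour 2 (81.2 to 81.8%) and 89.5% in tumour 3 (89.3 to 89.7%). Ighm, the unswitched isotype, held 8.19% ± 0.880, and Ighe held 5.36% ± 4.22 with its highest share, 10.2%, in tumour 2. Ighg1, the locus that drives Cre, held 0.246% ± 0.125, Ighg2b 0.194% ± 0.123 and Igha 0.0903% ± 0.0146. Ighd had 151 counts in tumour 1 against 6 and 5 in tumours 2 and 3. Among isotypes other than Ighm and Ighd the share of Ighg3 was 93.3%. Over all heavy-chain constant genes it was 80.7% after division of counts by gene length. These are shares of counts. Counts per gene do not show whether a constant transcript carries a V gene, so the shares do not measure switched or unswitched cells.

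The kappa constant gene Igkc held 84.1% ± 1.89 (SD, n = 3) of light-chain constant counts. The lambda genes Iglc1, Iglc2 and Iglc3 held 7.01% ± 1.78, 5.87% ± 0.912 and 3.01% ± 0.648. Counts on lambda V genes were few, with 55, 21 and 27 in tumours 1, 2 and 3, too few for shares under the minimum set. The number of kappa V counts was 13378, 16751 and 18744.

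A single heavy-chain V gene and a single kappa V gene led in every tumour. Ighv8-11 (ENSMUSG00000095170.2, chromosome 12, 115567149 to 115567591) held 79.6% ± 4.85 (SD, n = 3) of Ighv counts. Its share was 74.1% (72.9 to 75.2%), 81.5% (80.2 to 82.7%) and 83.2% (82.3 to 84.1%) in tumours 1, 2 and 3. The second gene in each was the related Ighv8-8, with 13.7%, 11.8% and 14.5%, and reads could be split between such paralogs. Igkv6-17 (ENSMUSG00000095794.2, chromosome 6, 70371439 to 70371993) held 97.1% ± 3.34 of Igkv counts, from 93.3% (92.9 to 93.7%) in tumour 1 to 99.4% (99.3 to 99.5%) in tumour 3. The joining genes that led were also shared, with Ighj4 at 97.0% ± 2.99 of Ighj counts and Igkj1 at 80.1% ± 9.50 of Igkj counts. The effective number of Igkv genes (inverse Simpson index) was 1.149, 1.026 and 1.012. The files list 112 Ighv and 99 Igkv genes.

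**Figure D1:**
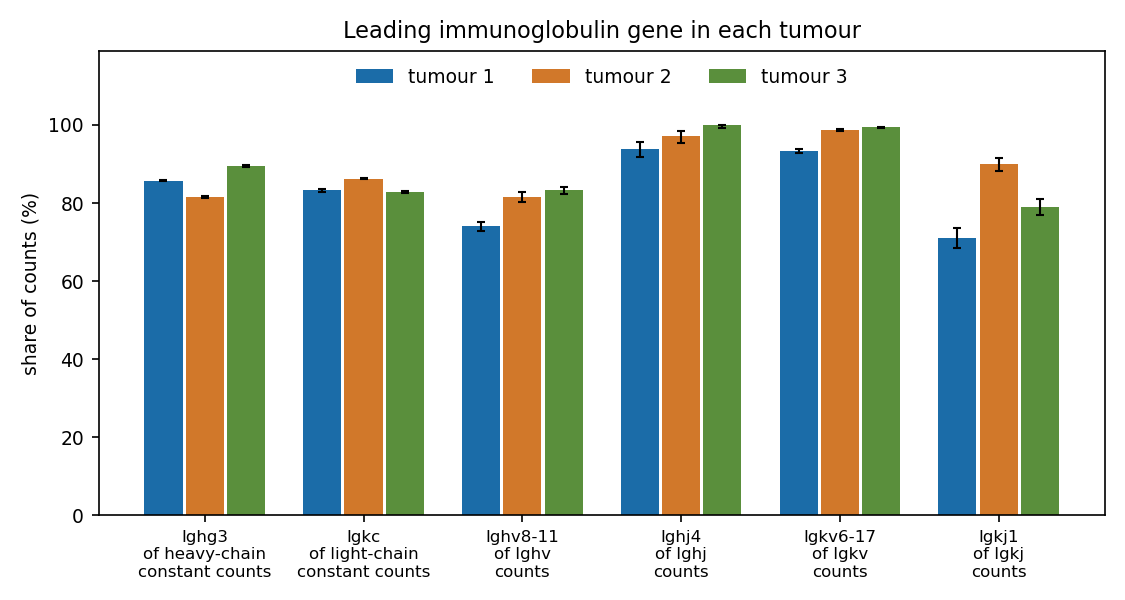
Share of counts (%, vertical axis) held by the leading immunoglobulin gene of each class in tumours 1, 2 and 3, as bars with 95% Clopper-Pearson intervals that cover counting error only. The same gene led each class in all 3 tumours, with Igkv6-17 between 93.3% and 99.4% and Igkj1 between 71.1% and 90.1%.

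The libraries held a broad B cell programme. All 18 pan-B genes reached 1 CPM in every tumour, with a list median of 338.7 CPM, above all but a negligible share of random lists (percentile 100). Cd37 had 685 ± 201 CPM, the B cell coactivator gene Pou2af1 394 ± 25.4 CPM, and the receptor chains Cd79b and Cd79a 318 ± 94.6 and 236 ± 116 CPM. All 12 genes of B cell receptor signalling were also above 1 CPM, with Blnk at 504 ± 16.8 CPM and Plcg2 at 281 ± 43.8 CPM. The pan-B median exceeded the T cell median by 6.46 ± 0.66 in log2(TPM + 1), 88.1-fold, in 3 of 3 tumours (exact sign-flip p = 0.25, the smallest possible).

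Genes that mark the ABC subtype in human classification assays stood well above those that mark the germinal centre B cell (GCB) subtype. Of 8 ABC assay genes 7 reached 1 CPM in all tumours (median 131.6 CPM), against 4 of 7 GCB assay genes (median 6.16 CPM). Ccdc50 had 323 ± 153 CPM, the receptor gene Tnfrsf13b 248 ± 41.6 CPM and Limd1 192 ± 26.3 CPM, while Cyb5r2 was at 0.241 ± 0.305 CPM. Among GCB genes, Itpkb and Asb13 had 22.4 ± 9.99 and 20.97 ± 2.14 CPM, and Mme (CD10) and Serpina9 stayed below 1 CPM in every tumour. The ABC median exceeded the GCB median by 4.79 ± 0.56 in log2(TPM + 1), 27.7-fold, in 3 of 3 tumours, and Irf4 exceeded Bcl6 by 4.75 ± 0.51, 26.8-fold. Both had an exact sign-flip p of 0.25, also 0.25 after adjustment over the 6 differences computed. The GCB median averaged 1.41 in log2(TPM + 1), and with a pseudocount of 0.1 the ABC minus GCB difference was 5.38. These are levels within lymphoma cells, and the fold of each gene against normal germinal centre cells was not analysed here. The 5 reference genes of such assays all exceeded 10 CPM (median 60.4 CPM), led by R3hdm1 at 227 ± 48.7 CPM and Ubxn4 at 158 ± 18.7 CPM.

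Germinal centre genes lay below genes of the secretory plasma cell programme. Of 11 germinal centre genes 7 reached 1 CPM in all tumours, with a median of 6.16 CPM. That median stood at percentile 48.6 among random lists, and at 2.31 when those were drawn from genes above 1 CPM. Fas had 45.3 ± 7.96 CPM and Mef2b 22.3 ± 6.42 CPM, and Gcsam and Rgs13 lay at or under the count floor. Of 16 plasma cell genes 14 reached 1 CPM (median 91.2 CPM, percentile 99.98), among them the endoplasmic reticulum genes Txndc5 at 318 ± 71.9 CPM and Creld2 at 207 ± 60.2 CPM. The surface marker gene of plasma cells, Sdc1, was at 0.422 ± 0.0844 CPM. The germinal centre median lay below the plasma cell median, with a difference of -4.31 ± 0.56 in log2(TPM + 1) in 3 of 3 tumours (exact sign-flip p = 0.25, the smallest possible). The germinal centre and GCB assay lists share S1pr2 and Mybl1, and Mybl1 sets the median CPM of both. Irf4 is in the ABC assay and plasma cell lists. The ABC minus GCB, Irf4 minus Bcl6 and germinal centre minus plasma cell differences are thus not independent. Light zone genes (12 of 14 at 1 CPM, median 93.4 CPM) exceeded dark zone genes (7 of 7, median 47.4 CPM) by 1.44 ± 0.36 in log2(TPM + 1), with the same exact p. Myc led the former at 912 ± 122 CPM, and Cxcr4 led the latter at 88.2 ± 39.9 CPM. The light zone genes Cd83, Nfkbia, Cd40, Icam1, Traf1, Ebi3, Bcl2a1b and Bcl2a1d are also in the list of NF-κB targets. The light zone minus dark zone difference is thus not independent of the level of NF-κB targets.

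Lists of other B cell stages gave a mixed picture. Naive and follicular genes reached 1 CPM for 6 of 8 members (median 96.2 CPM), with Klf2 at 233 ± 134 CPM and Btla at 217 ± 91.3 CPM. Marginal zone genes did so for 5 of 7 (median 38.9 CPM), led by Notch2 at 279 ± 87.0 CPM. Memory B cell genes did so for 6 of 7 (median 21.3 CPM), led by Cd38 at 147 ± 54.5 CPM. Genes of age-associated B cells did so for 5 of 6 (median 41.7 CPM), and B1 cell genes for 6 of 7 (median 54.9 CPM). Zbtb32, a member of both of the last lists, had 164 ± 58.4 CPM, and the B1 regulator gene Bhlhe41 had 229 ± 79.4 CPM.

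NF-κB target genes were abundant. Of 26 members 24 reached 1 CPM in every tumour, with a median of 104.3 CPM and a level percentile of 100 among random lists. The inhibitor genes Nfkbia, Nfkbie and Nfkbid, which NF-κB itself induces, had 433 ± 61.2, 164 ± 60.7 and 155 ± 59.1 CPM, and Cd83 had 258 ± 78.2 CPM. Of 18 p53 target genes 13 reached 1 CPM, with a median of 24.02 CPM. Ccng1 had 120 ± 25.5 CPM, Btg2 108 ± 47.0 CPM, Pmaip1 94.4 ± 27.6 CPM and Bax 65.6 ± 23.4 CPM. Phlda3 lay under the count floor and Eda2r had no count. In the BCL2 family 12 of 14 genes reached 1 CPM (median 38.5 CPM), led by the survival gene Mcl1 at 609 ± 86.0 CPM, with Bak1 at 186 ± 31.3 CPM.

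Genes of proliferation and growth were high in all 3 tumours. All 16 G2 and M phase genes and all 14 S phase genes exceeded 10 CPM in every tumour, with medians of 101.7 and 173.8 CPM. Top2a had 518 ± 214 CPM, Ube2c 160 ± 78.7 CPM, and the replication helicase genes Mcm6 and Mcm5 had 432 ± 108 and 306 ± 74.4 CPM. All 13 MYC target genes exceeded 10 CPM (median 466.3 CPM), led by the nucleolar genes Ncl at 3289 ± 437 CPM and Npm1 at 1670 ± 482 CPM. All 10 genes of the unfolded protein response reached 1 CPM (median 273.4 CPM), led by the chaperone genes Calr at 1265 ± 351 CPM and Hspa5 at 1179 ± 322 CPM.

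Antigen presentation genes were among the most abundant transcripts. All 9 class II genes exceeded 10 CPM, with the invariant chain gene Cd74 at 9449 ± 1082 CPM, H2-Aa at 2895 ± 165 CPM, H2-Ab1 at 2524 ± 208 CPM and H2-Eb1 at 2061 ± 66.2 CPM. All 10 class I genes did too, with B2m at 3986 ± 807 CPM and H2-K1 at 1773 ± 323 CPM. Others of the 20 most abundant genes were Eef2 at 9433 ± 509 CPM, Hsp90ab1 at 6689 ± 449 CPM, Eef1a1 at 5703 ± 871 CPM, Actb at 3216 ± 1008 CPM, Ly6e at 2456 ± 373 CPM and Cd52 at 1174 ± 280.2 CPM. All 12 genes of immune checkpoint ligands reached 1 CPM (median 20.1 CPM). Cd274, which encodes PD-L1, had 207 ± 114 CPM, with 274, 75.3 and 273 CPM in tumours 1, 2 and 3, a spread that did not pass the edgeR variability test (adjusted p = 0.391). Cd47 had 209 ± 18.3 CPM. Interferon response genes were lower, with 11 of 16 at 1 CPM and a median of 6.22 CPM, with Zbp1 at 74.7 ± 48.0 CPM and Stat2 at 72.1 ± 20.6 CPM.

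**Figure D2:**
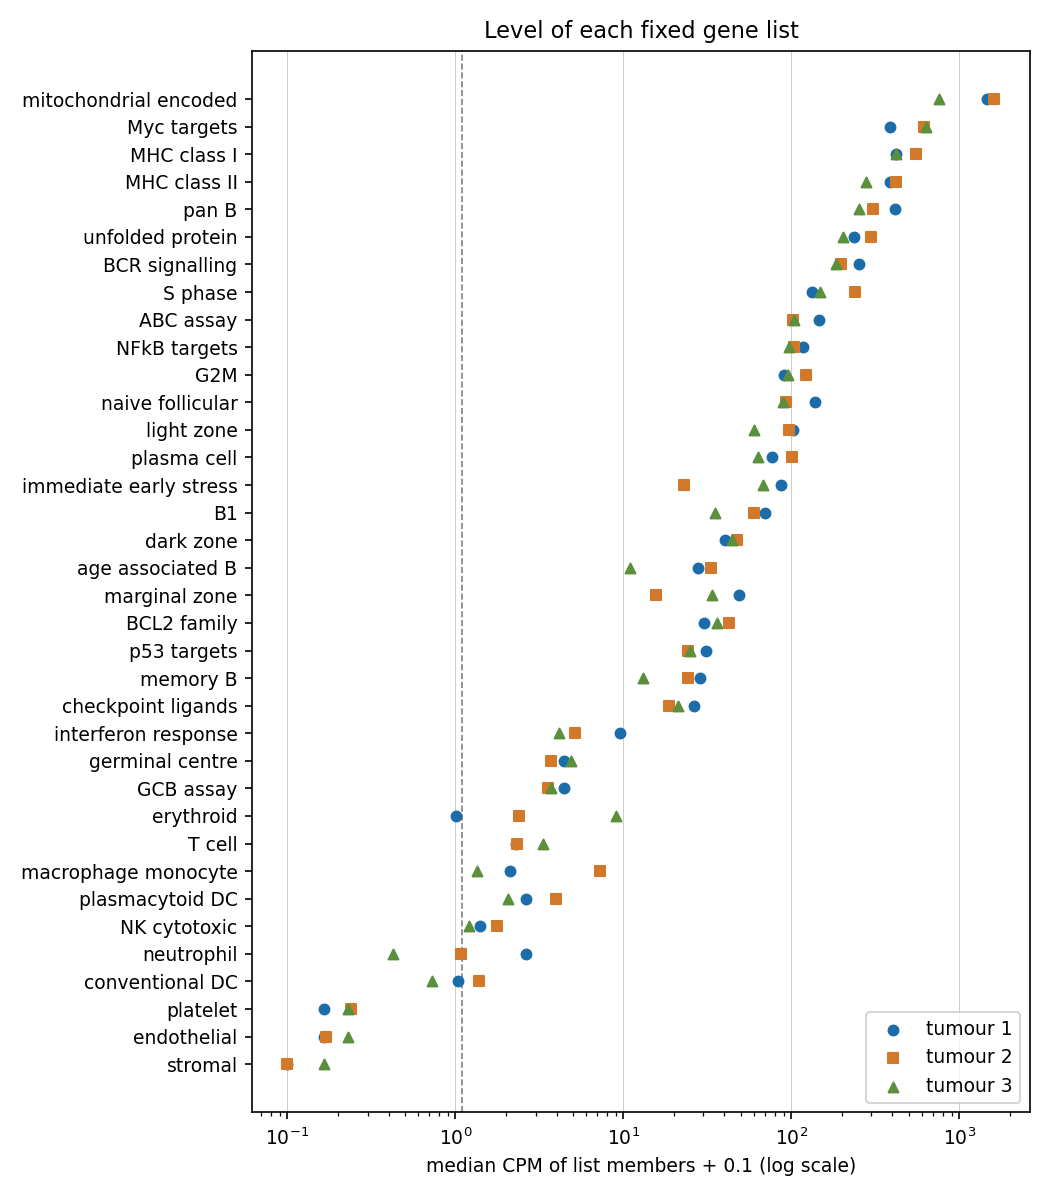
Median CPM of the members of each fixed gene list, plus 0.1, on a log horizontal axis, with 1 point per tumour and a dashed line at 1 CPM plus 0.1. Lists of MYC targets, antigen presentation and pan-B genes lie above 100 CPM in all 3 tumours, and platelet, endothelial and stromal lists lie below 1 CPM.

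Markers of other cells that the B220+GFP+ gate could hold were mostly low. Of 11 T cell genes 7 reached 1 CPM in all tumours (median 3.02 CPM), led by Cd8b1 at 32.9 ± 19.6 CPM, with Cd3g at 7.83 ± 4.12 CPM. Natural killer and cytotoxic genes did so for 4 of 8 (median 1.48 CPM), led by Gzmb at 10.3 ± 7.41 CPM, and conventional dendritic cell genes for 3 of 6 (median 0.949 CPM), led by Flt3 at 7.71 ± 4.49 CPM. Macrophage genes did so for 5 of 11 (median 2.93 CPM). Cd68 stood apart from them at 135 ± 9.97 CPM, while Fcgr1 was below 1 CPM. Of 11 neutrophil genes 0 reached 1 CPM in every tumour, but Ngp had 24.04, 5.91 and 0.981 CPM and S100a9 13.6, 6.82 and 0.588 CPM in tumours 1, 2 and 3.

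Plasmacytoid dendritic cell genes reached 1 CPM for 3 of 5, with Pacsin1 at 112 ± 27.8 CPM and the lineage marker Siglech at 0.660 ± 0.221 CPM. Erythroid genes did so for 4 of 9 (median 3.97 CPM) and platelet genes for 1 of 7, the integrin gene Itgb3 at 26.3 ± 14.7 CPM. Stromal genes did so for 1 of 8, Madcam1 at 58.0 ± 43.0 CPM, with Col1a1 at 0.600 ± 0.365 CPM. Endothelial genes did so for 2 of 9, Pecam1 at 146 ± 8.37 CPM and Egfl7 at 5.16 ± 4.02 CPM, with Kdr and Stab2 under the count floor. Of 13 mitochondrially encoded genes 7 reached 1 CPM, led by mt-Co1 at 17296 ± 1509 CPM, and the others, such as mt-Co2, were listed at or near 0. Xist, expressed from the inactive X chromosome, had 2302, 693 and 741 CPM in tumours 1, 2 and 3, and the 4 Y-linked genes lay under the count floor.

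The tumours resembled each other in rank order. Across the 11478 tested genes, which are not independent replicates, the Spearman correlation of log2 CPM was 0.956 between tumours 1 and 2, 0.952 between 1 and 3 and 0.949 between 2 and 3. Between these pairs 1494, 1637 and 1885 genes differed by more than 2-fold. The chi-square of raw counts per degree of freedom was 91.8, 85.1 and 83.3, so no pair agreed within sampling noise as a library deposited in duplicate would. This does not show that the tumours arose separately.

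Differences between tumours past the threshold were few. In the edgeR variability test 16 of 11478 genes had an adjusted p under the threshold of 0.05, and 720 had an unadjusted p below it. Of the 16 genes, 8 were highest in tumour 1, 5 in tumour 2 and 3 in tumour 3, and 8 were lowest in tumour 3. Ighg2c (chromosome 12, 113285325 to 113288932) had the smallest adjusted p, 0.0185, with 46.3, 1.32 and 0.981 CPM in tumours 1, 2 and 3, a 47.2-fold range.

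The chemokine gene Cxcl9, induced by interferon gamma, had 51.1, 106 and 5.62 CPM in tumours 1, 2 and 3, and its receptor gene Cxcr3 had 47.2, 276 and 36.9 CPM. The edgeR adjusted p was 0.0299 for Cxcl9 and 0.0363 for Cxcr3. The guanylate-binding protein gene Gbp2b (127, 151 and 9.09 CPM, adjusted p = 0.0234) and Samd9l (44.9, 9.95 and 2.03 CPM, adjusted p = 0.0490) were also lowest in tumour 3. Jchain, which encodes the joining chain of secreted polymeric antibody, had 35.6, 414 and 233 CPM (edgeR adjusted p = 0.0363), an 11.6-fold range. With a per-library trend on gene length and GC content removed, an alternative chosen after seeing the data, the edgeR adjusted p of Samd9l was 0.0550 and that of Prr7 was 0.0644, so neither passed the threshold. Arrdc4 and Prr7 were highest in tumour 3, at 52.3 and 34.5 CPM, and the chromatin remodeller gene Chd3 was highest in tumour 1, at 65.2 CPM. Also past the threshold were Gm30198, Gm1966 and Gm36043, which have provisional symbols and were named after their values were seen. Gm36043, with 66.7, 3.76 and 43.5 CPM, lies inside Cd274 on the opposite strand. The use of strand is not given, so reads of Cd274 could have been counted on it.

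Of the 24 genes with characterised symbols and the smallest p, 12 passed the threshold. The other 12 had an edgeR adjusted p of 0.0536 and are not called. They included Nid1 with 479, 121 and 65.7 CPM, Serpinb6b with 892, 1283 and 166 CPM, Nr4a1 with 86.2, 7.79 and 33.3 CPM and Hba-a1 with 1.75, 7.10 and 37.7 CPM.

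The 16 calls depend on the filter for low counts, although all 16 genes pass the filters below, and on single libraries. With a filter on mean count of at least 10, chosen after seeing the data, edgeR called 0 genes (smallest adjusted p 0.121, 781 genes at unadjusted p under 0.05). It also called 0 with a filter at a mean of 5 CPM (614 unadjusted), 0 without tumour 1 (654 unadjusted) and 0 without tumour 2 (606 unadjusted), while the chi-square test against the DESeq2 dispersion trend called 56.

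**Figure D3:**
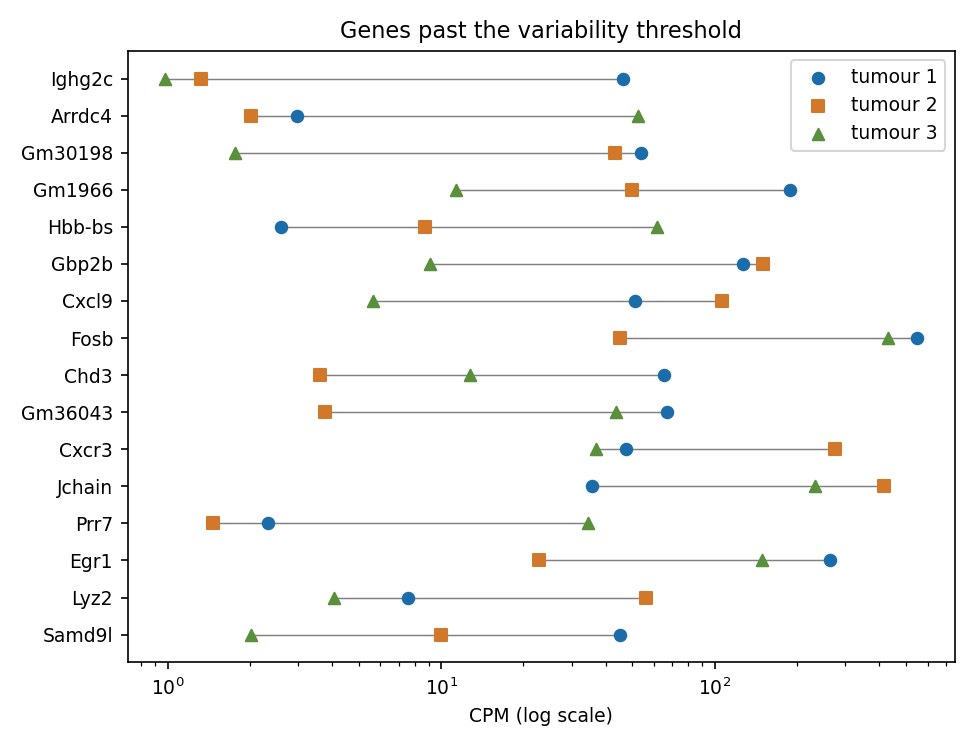
CPM (log horizontal axis) of the 16 genes past the variability threshold, ordered by p from the top, with 1 point per tumour and a line over the range. Ighg2c spans 0.981 to 46.3 CPM, and Fosb and Egr1 are lowest in tumour 2.

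Immediate early genes, which respond within minutes to signals and to handling, set tumour 2 apart. Fosb had 550, 45.0 and 428 CPM in tumours 1, 2 and 3, and Egr1 had 264, 22.7 and 149 CPM, with edgeR adjusted p of 0.0337 and 0.0372. Of 10 tested members of this list 2 passed the threshold over all genes and 8 passed it adjusted over the list alone. The list was the 1 of 38 with an excess of variable genes by Fisher's exact test (adjusted p = 0.0031). That excess rests on these 2 genes, which are often expressed together, and with the filter on mean count their edgeR adjusted p was 0.139 and 0.140. Its median deviation was 0.72, -1.58 and 0.62 in log2 CPM in the 3 tumours, each outside the central 95% of matched random lists. Fos had 244, 51.4 and 289 CPM and Jun 259, 54.9 and 249 CPM, neither past the threshold over all genes.

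Among markers of other cells, 1 macrophage gene and 1 erythroid gene passed the threshold over all genes, and 0 genes of the other marker lists did. Adjusted over the list alone, 2 of 5 tested macrophage, 5 of 7 erythroid, 2 of 2 neutrophil and 1 of 1 stromal genes passed. In the T cell, natural killer, dendritic cell, platelet and endothelial lists 0 genes did. With 1 or 2 tested members this adjustment corrects little or nothing. The neutrophil genes were Ngp and S100a8, highest in tumour 1 (6.93, 3.83 and 0.654 CPM for S100a8), and the stromal gene was Madcam1, highest in tumour 2 at 108 CPM. Over all genes their edgeR adjusted p was 0.120, 0.630 and 0.397. None of these lists had an excess of variable genes by Fisher's exact test (adjusted p = 0.088 for macrophage and 0.0923 for erythroid genes). The macrophage gene Lyz2 had 7.58, 56.2 and 4.05 CPM (edgeR adjusted p = 0.0372), and Hmox1 had 7.45, 44.8 and 4.58 CPM (adjusted p = 0.0856). The median deviation of the macrophage list in tumour 2 was 1.43 in log2 CPM, above all of the matched random lists to rounding, in the tumour in which Cxcl9, Cxcr3 and Jchain were highest. That of natural killer and cytotoxic genes, from 4 tested members, was 0.92 in tumour 2 and -1.003 in tumour 3. The adult haemoglobin gene Hbb-bs had 2.59, 8.70 and 61.7 CPM (edgeR adjusted p = 0.0234), and the erythroid list deviated by 1.82 in tumour 3 and by -1.68 in tumour 1. T cell genes deviated by 0.44 in tumour 3.

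Of 99 pairs of a list and a tumour, 38 lay outside the central 95% of matched random lists, against 4.95 by chance for independent lists. Members of a list are co-expressed and random genes are not, so this number is not a test. In tumour 1 the pan-B list deviated by 0.50, marginal zone genes by 0.85, age-associated B cell genes by 0.66, interferon response genes by 0.60, receptor signalling genes by 0.34 and NF-κB targets by 0.26. In tumour 2, S phase genes deviated by 0.44, plasma cell genes by 0.37 and unfolded protein response genes by 0.37. In tumour 3 the deviations were -0.42 for pan-B, -1.08 for age-associated B cell, -0.83 for interferon response, -0.58 for memory B cell, -0.48 for B1 and -0.45 for unfolded protein response genes. Lists of MYC targets, class II, class I, BCL2 family, p53 target, dark zone, ABC and GCB assay, assay reference, checkpoint ligand, mitochondrially encoded, and conventional and plasmacytoid dendritic cell genes lay within the central 95% in all tumours. With the length and GC trend removed, 41 pairs lay outside. In tumour 1 the ABC assay, class II and checkpoint ligand lists were then outside, at percentiles 99.95, 99.3 and 98.1, and class II deviated by 0.10 where it had deviated by -0.01. Among the 292 distinct list genes tested, 6 were past the threshold over all genes and 23 were past it when the adjustment ran over these 292 genes as 1 set.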

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

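Alternatives on gene length and GC content, on the filter by mean count and on list levels in TPM with release M21 lengths were chosen only after the results were seen. The others, TPM without immunoglobulin and mitochondrial genes included, were planned. Of the alternatives of the main results, 121 left the value where it was within its spread or within 1.5 times the count. Of the others, 5 moved it, 3 raised a count, 6 lowered one and 1 turned a direction. Omission of 1 tumour cannot move a mean of 3 by more than its SD. It also cannot lower a count of members that reach 1 CPM in every tumour. Many of the 121 were thus fixed beforehand, and their number does not measure how stable the results are. The count of variable genes, 16, was the least stable. It was 164 without a filter on low counts, where 25500 genes were tested and the prior degrees of freedom became infinite, and all 16 genes were among them. It was 94 with a chi-square test against the edgeR trend, again with all 16, and 56 against the DESeq2 trend, with 12 shared. It was 0 with a mean of at least 5 CPM and 0 with a mean count of at least 10, and it ranged from 0 to 11 when each tumour was left out, 11 without tumour 3 with 6 shared. The 16 genes pass both of these filters on the mean, so they were still tested. The prior degrees of freedom were 11.7 with the filter at 5 CPM and 11.1 with that on mean count, against 15.8 in the main fit. Whether that change alone removed the calls was not tested. Fewer samples leave 1 residual degree of freedom when a tumour is left out. DESeq2 size factors gave 15 and removal of immunoglobulin genes 14, all among the 16.

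The share of Ighg3 was 80.7% and that of Ighm 10.3% after division by gene length, and Ighg3 was 93.3% without Ighm and Ighd, by construction of the share. Ikbkb minus Chuk turned from -0.43 to 1.46 with CPM, because the larger union exon length of Ikbkb is then not divided out. That length covers all annotated transcripts, so the direction is not settled. Over the 6 differences between genes or lists, 29 of 30 values under alternatives kept their direction. Each difference had the same sign in all 3 tumours, so omission of 1 could not turn it. The lowest Spearman correlation between tumours was 0.909 without a filter, which adds genes near 0, and from 0.949 to 0.956 when each tumour was left out. The number of list and tumour pairs outside the random lists ranged from 22 to 27 when each tumour was left out, against 38 with all, where 1 tumour fewer also leaves fewer pairs. Level percentiles of lists moved under 44 alternatives and stayed under 32. Depth limits statements below 0.194 to 0.209 CPM, the level of 3 counts. Simulated changes of 4-fold were recovered for only 13.2% of genes. The simulation used another filter than the main test, so that rate does not carry over to it. No paired analysis was possible because all samples belong to 1 group and the numbers of the tumours come from accession order.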

Other observations

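The tests of shared V and J genes, of reads assigned to related Igkv genes and of the length trend as the whole cause were chosen only after the result was seen, and the families in the next paragraph were chosen in the same way. The test of other B cells and that of unspliced RNA had their outcomes written down beforehand.

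Guanylate-binding proteins and immunity-related GTPases, large GTPases of cell-autonomous defence that interferon gamma induces, were lowest in tumour 3. Of 11 tested Gbp genes 9 were highest in tumour 1 and 9 lowest in tumour 3, with 2818, 2224 and 787 CPM in total in tumours 1, 2 and 3. Gbp2 had 1293, 1054 and 213 CPM, and Gbp2b was the 1 member past the edgeR threshold. All 4 tested immunity-related GTPases, Irgm1, Irgm2, Igtp and Iigp1, were lowest in tumour 3, where their median deviation was -1.03 in log2 CPM, with 0 past the threshold. In that tumour the natural killer and cytotoxic list deviated by -1.003, while the macrophage list deviated by -0.63, 1.43 and -0.57 in tumours 1, 2 and 3. The former value rests on 4 tested members, Gzmb, Nkg7, Prf1 and Eomes. The natural killer genes Ncr1 and Klrb1c stayed below 1 CPM in every tumour, so no difference in natural killer cells is shown. Gbp genes are near-identical in places, so reads can be split between them. The numbers of members highest in tumour 1 and lowest in tumour 3 were the same with DESeq2 size factors and with raw library sizes. Those scalings shifted the median of all tested genes by -0.058 in log2 at the most, so this is a weak check. The median deviations of the 4 GTPases in tumours 1 and 2 changed order, from 0.49 and 0.54 to 0.53 and 0.48 with raw library sizes. Once a per-library trend on gene length and GC content was removed, 8 Gbp genes were highest in tumour 1, and 9 of 11 Gbp genes and all 4 of these GTPases were lowest in tumour 3.

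Ribosomal protein genes were taken by symbol, as Rpl or Rps followed by a digit. Such symbols include other genes, such as kinases named Rps6k, so the set may not be ribosomal proteins alone. Of 107 tested members 87 were lowest in tumour 1 and 82 were highest in tumour 2, with 0 past the edgeR threshold. Their median deviation was -0.31, 0.27 and 0.07 in log2 CPM in tumours 1, 2 and 3, and -0.28, 0.21 and 0.10 with raw library sizes. Most are short, 70 of 107 lying in the shortest of 5 length bins, and the genes of that bin deviated by a median of -0.21, 0.21 and 0.03. With the length and GC trend removed, the ribosomal protein medians were -0.20, 0.16 and 0.05, with 75 members lowest in tumour 1 and 67 highest in tumour 2. Of 9 tested Gimap genes, GTPases of lymphocytes, 5 were highest in tumour 2 and 6 lowest in tumour 3. Of 12 tested histone genes 9 were lowest in tumour 1 and 9 highest in tumour 3, with 0 past the threshold, in libraries selected for polyadenylated RNA. With the trend removed, 6 were lowest in tumour 1 and 10 highest in tumour 3, and 5 Gimap genes were highest in tumour 2 and 5 lowest in tumour 3.

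The first pattern is that Ighv8-11, Ighj4, Igkv6-17 and Igkj1 led in all 3 tumours. Carry-over of reads between libraries would bring every gene along with Igkv6-17, which had 12481, 16539 and 18629 counts in tumours 1, 2 and 3. Single genes, picked from the 16 variable ones, argue against it as the source of that whole signal. Ighg2c had 714 counts in tumour 1 against 19 and 15. Lyz2 had 808 in tumour 2 against 117 and 62, and Arrdc4 had 800 in tumour 3 against 46 and 29. In each of the 6 ordered pairs of libraries at least 9.75% of tested genes lay below 0.9 times the level carry-over would bring. Counting error was not allowed for, so that share alone does not decide. Counting that sees only these V genes is argued against in tumour 1 by 27 other Igkv genes with 10 or more counts. In tumours 2 and 3 only 4 and 2 such genes were found. Taken strictly it is argued against there too, by 212 and 115 counts on other Igkv genes where it allows none. Counting that misses part of the reads of other V genes stays open. A common B cell clone, for instance by transplantation of a primary tumour, is a hypothesis that these counts cannot test, because the shared leading gene in 2 of 2 J families is part of the pattern itself. Independent clones with alike receptors stay open too, as counts hold no junction sequences and the labels name neither a receptor transgene nor the relation between the animals.

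The second pattern is a set of minor immunoglobulin transcripts in tumour 1, where other Igkv counts were 7.19% of those on Igkv6-17, against 1.28% and 0.617% in tumours 2 and 3, and where Ighd, Ighg2c and Cr2 were highest. Reads of Igkv6-17 assigned to its relatives are argued against, since only 7.92% of the other Igkv counts in tumour 1 lay on Igkv6 genes. Other B cells in the sort of tumour 1 may be the source, as the minor counts there spread over an effective number of 22.3 Igkv genes. That number was 16.3 in tumour 2 and 5.87 in tumour 3, so such a spread was not particular to tumour 1. The GFP gate was meant to remove such cells, and minor lymphoma subclones with other receptors stay open.

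The third pattern is that long genes were higher in tumour 1 and lower in tumour 2. Across 11470 genes, which are not independent, the Spearman correlation of deviation with exon length was 0.399, -0.336 and -0.0352 in tumours 1, 2 and 3, and genes in the longest of 5 length bins deviated by 0.24 and -0.21 in tumours 1 and 2. This trend as the whole cause of the variable genes is argued against, since 14 of the 16 genes, without Prr7 and Samd9l, stayed past the threshold once it was removed, when 22 were called. More unspliced or nuclear RNA in the library of tumour 1 stays a possible explanation of the trend, as the share of counts on sense-intronic and unconfirmed (TEC) genes there was 1.285 times the higher of the others. RNA integrity per library was not analysed here, and with 1 group no biological difference between groups was tested for any of the 3 patterns.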
